A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

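RNA was measured in 8 libraries of the budding yeast Saccharomyces cerevisiae, 2 biological replicates in each of 4 groups. Per the labels, the strain was W303 with PDR1 and PDR3 deleted, the genes of a related pair of transcription factors that switch on drug-efflux pumps. Log-phase cultures in galactose medium received the DMSO solvent, clioquinol (CQ, an 8-hydroxyquinoline that binds metal ions) or 1 of 2 DHPM-thiones (dihydropyrimidine-thiones) for about 6 h. CQ was given at 0.8 µM and each thione at 20 µM. The thione 10{3,3,1} is the active compound of the labels and the thione 11 the inactive one. The growth protocol states the concentrations in millimolar and calls the yeast wild-type, while the sample characteristics and the series design state micromolar and the strain label names the deletions. The micromolar values and the deletion strain are used below. Per the labels' protocols, total RNA was extracted with hot acid phenol, libraries were made with the PrepX RNA-Seq kit and sequenced on an Illumina HiSeq instrument.

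The authors deposited a table of raw read counts per annotated feature, with 1 column per library. Per the submitters' processing notes, TopHat, TopHat2 2.1.1, HTSeq and DESeq were used with the sacCer3 genome build. The annotation, the counting mode and the strand setting are not given in the sources used here, so reads from a gene and from an overlapping or antisense feature may not be separable. The same deposited table holds normalized values, a signal made by the authors by dividing each count by 1 size factor per library. Those factors, read off features with more than 200 counts, were the same to 4 decimals as median-of-ratios factors recomputed from the raw counts in 7 libraries, and 1.0166 against 1.0165 in CQ replicate 2. The normalized values served only for that check. The table lists 7122 features, of which 725 have no count in any library. Another 4 lines of the copy used here are empty and were not analysed. Names and coordinates come from the RefSeq annotation of assembly R64, which corresponds to sacCer3. It names 6045 of the features, and the other 1077 keep the identifier of the table. That annotation has no untranslated regions, so gene coordinates span start to stop codon.

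Library totals ran from 12076141 to 19021672 counts. Replicates were compared before use. The chi-square per degree of freedom between the 2 libraries of a group was 22.8 in DMSO, 102.8 in CQ, 54.1 with the active and 45.0 with the inactive thione, so each pair differed by far more than sampling noise and counted as 2 samples. A gene with 0 counts could have had up to 3 counts by chance, which is 0.158 CPM (counts scaled to a common library total) in the largest library and 0.248 in the smallest. Such limits cover counting error only.

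Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the raw counts, two-sided, with TMM scaling, the filterByExpr filter and 1 term per group. All 8 libraries entered 1 fit because a pair of replicates gives a weak estimate of the spread on its own. The filter kept 5696 features, and the common biological coefficient of variation was 0.1526. Standard errors (SE) are the log2 fold change divided by the square root of its F value, and 95% intervals use the total degrees of freedom of the fit. P-values were adjusted by the Benjamini-Hochberg method over all tested features, with 0.05 as threshold, and a gene is said to rise or fall only past that threshold. A fold against a group with 0 counts in both libraries is a lower bound, computed with a summed count of 3 over both libraries.

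Gene lists were fixed before the data were examined. There were 34, covering metal, phosphate, stress, growth, respiratory and metabolic regulons and markers of other cell states. Lists with at least 3 tested members were tested against all other features with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Calls were repeated with an estimated correlation and with fry. The named genes also follow a rule fixed in advance. For CQ against DMSO, active thione against DMSO and active against inactive thione these were up to 10 genes with the largest rise and 10 with the largest fall, at an average log2 CPM of at least 3 and with both libraries of a group beyond both of the other. For the other 2 comparisons up to 5 each way were taken. Added to these were up to 4 members with the smallest p of each called list, any member of the Aft1/Aft2, Mac1, Cup2 and Zap1 lists, and PDR1 and PDR3. Genes named outside that rule are marked as chosen after their values were seen.

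The procedure was tested on simulated counts with 100 features changed 2-fold and 100 changed 4-fold among 5696. For CQ against DMSO it recovered 77% of the 2-fold and 96% of the 4-fold changes and called 0.33% of unchanged features. For the active thione against DMSO those values were 73%, 99% and 0.31%, for the inactive thione against DMSO 79%, 97% and 0.18%, and for the active against the inactive thione 81%, 97% and 0.31%. In each of these 4 simulated comparisons all 20 shifted lists and 0 of 20 unshifted lists were called. The simulated features varied independently and the lists were drawn at random. The simulation therefore says nothing about false calls of lists whose members are correlated. Alternatives were other size factors, no filter, DESeq2 1.42.0, a fit of the compared groups alone, a replicate block, stricter thresholds and leaving out each library in turn. The comparison restricted to features with a RefSeq entry was added after the data were seen. Enrichment of gene ontology terms and of a sequence element was tested with hypergeometric and Fisher's exact tests in Python 3.11.15 with scipy 1.17.1. On 20 random gene sets the term test called 0, it recovered 20 of 20 planted terms, and the element test called 4 of 100 random sets.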

Results

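The series asked how yeast cells respond to clioquinol, a known metal chelator, and to a DHPM-thione, with a related inactive thione and the solvent as controls. Transcripts were counted in 2 libraries per group. The DMSO libraries held 19021672 and 12839597 counts, the CQ libraries 18717883 and 14498843, the active thione libraries 12076141 and 14437085 and the inactive thione libraries 14187145 and 13404005. Each library detected 6046 to 6136 features. The 10 most abundant features took 7.63% to 8.85% of the counts, and ribosomal RNA features took at most 0.0011%. PDR1 and PDR3, the genes stated to be deleted, had 0 counts in all 8 libraries, which allows at most 0.248 CPM in the smallest. The metallothionein genes CUP1-1 and CUP1-2 also had 0 counts in every library. They are near-identical copies whose reads the counting may have dropped, so no level is given for them. The first principal component of log2 CPM held 60.2% of the variance and set the CQ libraries apart from the other 6. The second held 17.1%, with the DMSO libraries at 22.9 and 11.1 and the 6 treated libraries between -19.3 and 2.33.

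CQ at 0.8 µM raised the genes of iron uptake. Of the 33 members of the Aft1/Aft2 iron regulon, the genes switched on when iron is short, 31 rose, 1 fell and 1 did not pass, with a median log2 fold change of 2.71. FIT3, a cell-wall protein that holds iron-bearing siderophores, went from 16.1 ± 2.14 to 5264 ± 646 CPM (SD, n = 2), 327-fold higher. FIT2 rose 258-fold and the reductase gene FRE5 429-fold, the latter from only 1 and 5 counts in the DMSO libraries. These 3 genes are neighbours on chromosome XV in R64, FIT2 at 1059531 to 1059992, FIT3 at 1060441 to 1061055 and FRE5 at 1061564 to 1063648. The siderophore transporter genes ARN2, SIT1, ENB1 and ARN1 rose 87.1-fold, 39.6-fold, 38.8-fold and 28.2-fold, and FIT1 rose 26.8-fold. TIS11, whose product (also called Cth2) destabilises messages of iron-using proteins, rose from 2.13 ± 0.414 to 272 ± 12.8 CPM (SD, n = 2), with a log2 fold change of 7.01 ± 0.29 (SE) and an edgeR adjusted p of 4.55e-07. It lies on chromosome XII at 415801 to 416658. FET3 and FTR1, the high-affinity iron uptake pair, rose by 3.65 ± 0.17 and 2.97 ± 0.16 on the log2 scale (SE). LSO1 had 0 counts in DMSO and was at least 15.4-fold higher, with edgeR adjusted p = 0.00918, a call that DESeq2 did not make (adjusted p = 0.366, the highest of its alternatives, with 0.00671 the lowest). With LSO1 at that bound the list median stayed at 2.71. VHT1, HMX1, ATX1, ISU1 and ISU2 lost their calls without DMSO replicate 2, with log2 fold changes of 1.04, 1.25, 0.99, 0.76 and 1.02. ATX1, ISU1 and ISU2 also lost them without DMSO replicate 1 (1.16, 0.84 and 1.42), and ISU1 and ISU2 without CQ replicate 2 (0.64 and 0.79). With the compared groups alone ATX1 and ISU2 did not pass (edgeR adjusted p = 0.0512 and 0.0683). BIO5, a biotin-pathway transporter, fell by 2.03 on the log2 scale, and LEE1 did not pass (edgeR adjusted p = 0.14). The camera test put the list above the other features with adjusted p = 7.08e-98, and 0.00226 with an estimated correlation. Adjusted over the list alone, 32 members rose and 1 fell.

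**Figure D1:**
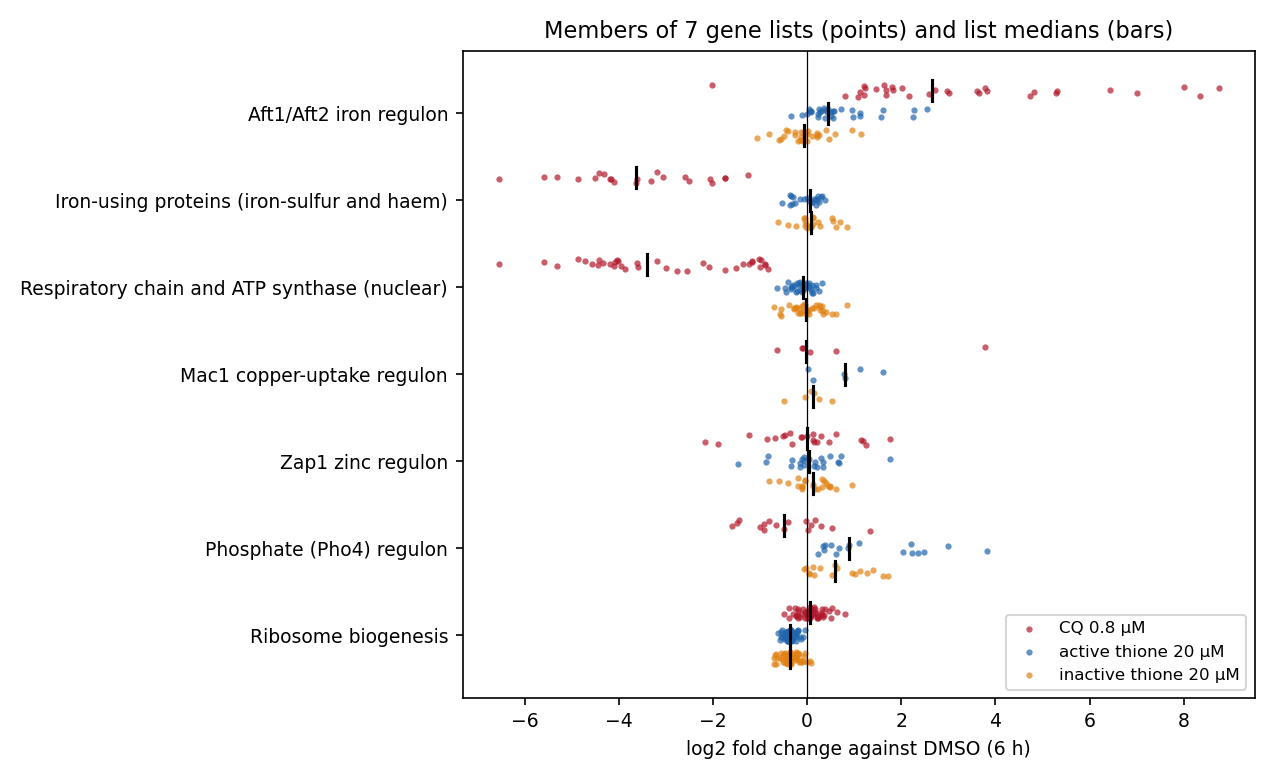
Each point is the log2 fold change of 1 member of 1 of 7 gene lists against DMSO (horizontal axis, log2 units), in red for CQ, blue for the active and orange for the inactive thione, and each bar is the median of the points drawn. LSO1, with 0 counts in 3 groups, is not drawn. The CQ medians of the iron-using and respiratory lists lie at -3.63 and -3.39, while the thione medians of these lists lie between -0.09 and 0.09.

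Genes for proteins that use iron and for respiration fell with CQ. All 22 members of the iron-using list (mostly iron-sulfur and haem proteins, with others such as RNR2, RNR4 and SDH1) fell, with a median log2 fold change of -3.63. Of the 36 nuclear genes of the respiratory chain and ATP synthase, 35 fell and 1 did not pass over all features, with a median of -3.39, and all 36 passed when adjusted over the list alone. The lists share 7 genes. CYC1, the gene of cytochrome c on chromosome X at 526335 to 526664, went from 112 ± 1.94 to 1.17 ± 0.327 CPM (SD, n = 2), a 93.8-fold fall. Also named by the rule were COX26, CYT1, RIP1, CIR2, YER053C-A, SDH2, QCR10, CYB5 and NDI1, with log2 fold changes from -5.79 (COX26) to -4.57 (NDI1). Among iron-sulfur enzymes outside respiration, LEU1 of leucine synthesis had a log2 fold change of -4.32 ± 0.18 (SE) and an edgeR adjusted p of 4.55e-07, and ACO1 (aconitase) one of -4.50 ± 0.21. Camera gave adjusted p = 1.63e-100 for the iron-using and 2.41e-87 for the respiratory list. With an estimated correlation these were 0.00205 and 0.0319.

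**Figure D2:**
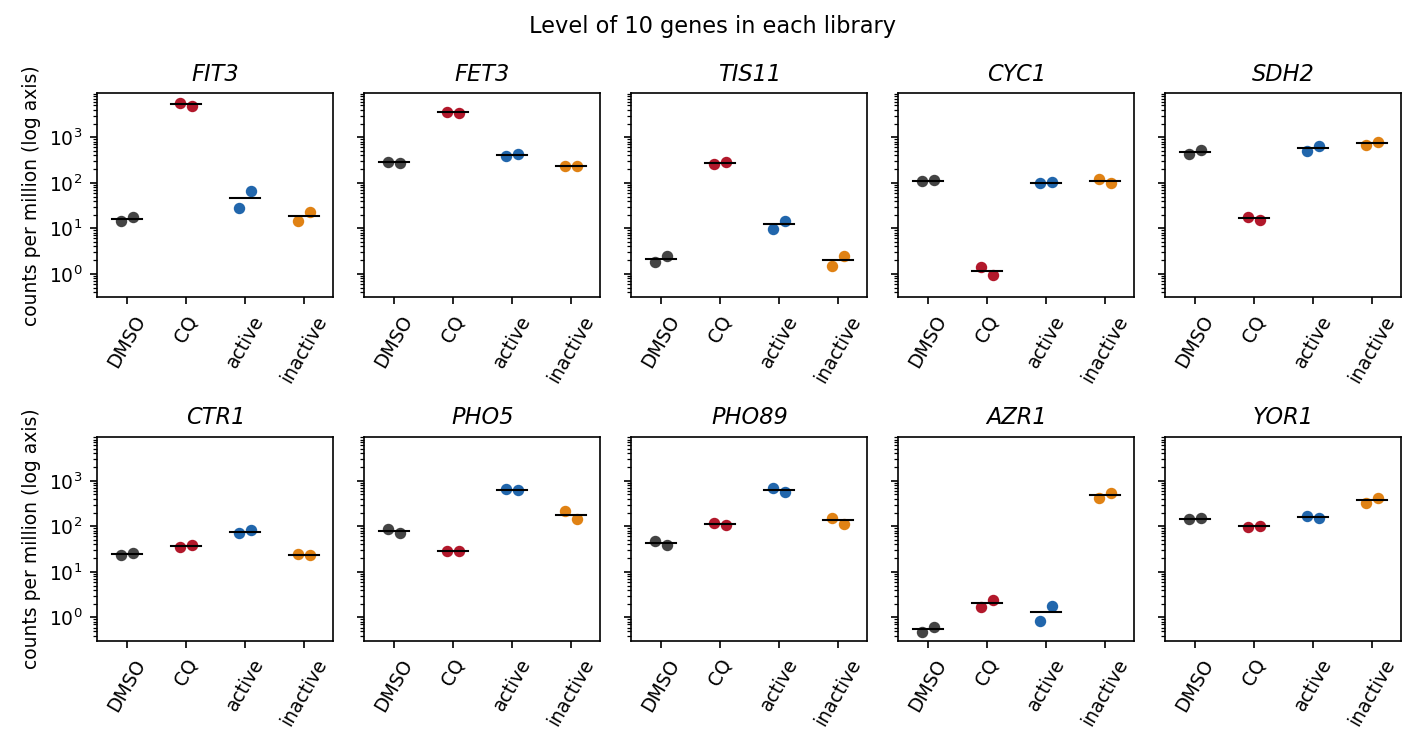
Each point is the level of a gene in 1 library, in CPM on a log axis, for DMSO, CQ, active and inactive thione, and each line is the mean of 2 libraries. FIT3, FET3 and TIS11 are high and CYC1 and SDH2 low in the CQ libraries, while AZR1 has 428 and 552 CPM in the inactive thione libraries and at most 2.41 CPM in the other 6.

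Other metabolic lists shifted less with CQ, and these calls were lost with an estimated correlation. Of 27 ergosterol genes 16 fell and 2 rose, 18 and 2 when adjusted over the list alone (median -0.91, camera adjusted p = 0.245 with an estimated correlation). The smallest p-values were those of ERG11, ERG1, ERG5 and CYB5, of which CYB5, ERG5 and ERG11 encode haem proteins. In the TCA and glyoxylate list 12 of 21 fell and 1 rose, 16 and 1 when adjusted over the list alone (camera adjusted p = 0.210 with an estimated correlation). In haem synthesis 5 of 8 members fell, 6 when adjusted over the list alone, including HEM15 and HEM13 (camera adjusted p = 0.287 with an estimated correlation). In the Yap5 list of genes for high iron CCC1 and GRX4 fell among 3 tested members (camera adjusted p = 0.0726 with an estimated correlation). In the amino acid list 10 of 43 fell and 2 rose, the same counts as when adjusted over the list alone (camera adjusted p = 0.475 with an estimated correlation). Its members LEU1, LYS4 and ILV3, with the smallest p-values, encode iron-sulfur enzymes. The biotin genes BIO2, BIO5 and BIO3 fell while VHT1 rose (camera adjusted p = 0.210 for the list with an estimated correlation). In the phosphate list 7 of 17 fell and 2 rose, 9 and 2 when adjusted over the list alone (camera adjusted p = 0.475 with an estimated correlation), with PHO5 and GIT1 lower and PHO89 higher by 1.34 on the log2 scale. All 4 genes specific to alpha cells fell (camera adjusted p = 0.0695 with an estimated correlation), of which STE3 lost its call without DMSO replicate 1 or 2 (edgeR adjusted p = 0.224 and 0.128), CQ replicate 1 (0.113) and inactive thione replicate 1 (0.0504), and MF(ALPHA)1 without DMSO replicate 1 (0.0982) and with the compared groups alone (0.0587). The hexose transporter genes HXT10, HXT5 and HXT2 rose, 3 of 7 (camera adjusted p = 0.383 with an estimated correlation), and of 32 proteasome genes RPT1 and RPT6 rose, 0 when adjusted over the list alone (camera adjusted p = 0.612 with an estimated correlation). Without CQ replicate 2 the camera adjusted p was 0.159 for the hexose and phosphate lists and 0.0604 for the proteasome, without DMSO replicate 1 it was 0.0889 for the phosphate list, and without the filter 0.106 for the hexose list. With the replicate block the camera adjusted p of the phosphate list was 0.0576. Member counts of several of these lists moved as well. The phosphate list, for example, had 1 riser and 3 fallers without DMSO replicate 1 and 2 and 4 without CQ replicate 1, the amino acid list 0 and 7 without DMSO replicate 1 or 2, and the proteasome 0 and 0 without DMSO replicate 1 or 2 and 5 and 1 without CQ replicate 2. RPT1 lost its call without DMSO replicate 1 or 2 or CQ replicate 1 (edgeR adjusted p = 0.258, 0.107 and 0.0741), and RPT6 without each library except CQ replicate 2 (0.0528 to 0.328), without the filter (0.0633) and with the compared groups alone (0.0923). BIO3 lost it without DMSO replicate 1 (0.0656) and VHT1 without DMSO replicate 2 (0.0514).

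Copper and zinc regulons did not shift in a common direction as sets with CQ. In the Mac1 copper-uptake list FRE1, which is also an Aft1 target, rose by 3.77 ± 0.16 and CTR1 by 0.61 ± 0.15 on the log2 scale (SE), while CTR3, FRE7, REE1 and IRC7 did not pass. The list median was -0.02 and its mean 0.60, so the camera call of a rise (adjusted p = 0.0126, and 0.245 with an estimated correlation) rests on FRE1. CTR1 lost its call without DMSO replicate 1 or 2 (edgeR adjusted p = 0.266 and 0.111), without CQ replicate 2 (0.0576), without inactive thione replicate 2 (0.050045) and with the compared groups alone (0.0946). Of 23 tested members of the Zap1 zinc regulon 5 rose and 5 fell, 6 and 7 when adjusted over the list alone, with a median of 0.0036 (camera adjusted p = 0.674). Over all features 758 of 5696 changed. Camera looks for a common direction, so a change of the zinc list in both directions stays open. The risers numbered 1 without DMSO replicate 1 and 3 without DMSO replicate 2 or CQ replicate 1, and the fallers 4 to 6 with any 1 library left out. The zinc transporter gene ZRT1 had a log2 fold change of 0.62 ± 0.16 and ZRT2 one of -0.68 ± 0.18 (SE). ZRT1 lost its call without DMSO replicate 1 or 2 (edgeR adjusted p = 0.163 and 0.204), CQ replicate 1 or 2 (0.0891 and 0.0568), active thione replicate 1 or 2 (0.0586 and 0.0583) and with the compared groups alone (0.0672), and ZRT2 without DMSO replicate 1 or 2 (0.233 and 0.0987) and CQ replicate 1 (0.150). SOD1 and CRS5, the only tested members of the Cup2 list, did not pass. In all, CQ changed 758 of 5696 features, 280 higher and 478 lower, of which 146 and 266 changed at least 2-fold. The count was 367 without DMSO replicate 1, 404 without DMSO replicate 2 and 1419 without CQ replicate 2, and 321 of the 758 features stayed called whichever library was left out.

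The active thione at 20 µM raised the phosphate regulon. Of its 17 members 8 rose and 0 fell, all 17 had fold changes above 0, and 16 passed when adjusted over the list alone, with a median log2 fold change of 0.89. PHO89, a sodium-phosphate transporter on chromosome II at 796798 to 798522, went from 43.7 ± 5.61 to 622 ± 79.2 CPM (SD, n = 2), 14.2-fold higher (edgeR adjusted p = 4.53e-05). The acid phosphatase gene PHO5, on the same chromosome at 429548 to 430951, rose by 2.99 ± 0.21 on the log2 scale (SE). GIT1, a transporter of glycerophosphoinositol, rose by 2.22 ± 0.16, SPL2 by 2.04 ± 0.18 and PHM6 by 2.35 ± 0.37. PHO5, PHO11 and PHO12 are similar genes between which reads may be shared. Camera gave the list adjusted p = 2.21e-44, and 0.0390 with an estimated correlation. The 8 risers became 4 without DMSO replicate 1 or 2 or active thione replicate 1 or 2. PHM6 lost its call without DMSO replicate 1 or 2 (edgeR adjusted p = 0.211 and 0.146) and without active thione replicate 1 or 2 (0.0974 and 0.140).

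Some genes of metal uptake also rose with the active thione. In the Aft1/Aft2 list 6 of 33 rose, 0 fell and 27 did not pass, and 10 rose when adjusted over the list alone. They were TIS11 (2.56 ± 0.28 on the log2 scale), FIT2 (2.25 ± 0.31), SIT1 (1.61 ± 0.26), ENB1 (1.13 ± 0.14), FRE1 (1.12 ± 0.15) and TMT1 (0.97 ± 0.16, all SE). TIS11 reached 12.3 ± 3.55 CPM (SD, n = 2). FET3 and FTR1 did not pass, with log2 fold changes of 0.54 and 0.08. Of 6 Mac1 genes CTR1, the copper transporter, rose by 1.62 ± 0.16 and FRE1 also rose, while 4 passed when adjusted over the list alone. Camera called both lists (adjusted p = 1.81e-11 and 5.17e-08), and neither call held with an estimated correlation (adjusted p = 0.101 for each). TIS11 and CTR1 lost their calls without DMSO replicate 1 (edgeR adjusted p = 0.0832 and 0.0788). FIT2, SIT1, ENB1, FRE1 and TMT1 lost theirs without DMSO replicate 1 (0.103 to 0.254), DMSO replicate 2 (0.109 to 0.177) and active thione replicate 2 (0.0731 to 0.163), and FRE1 and TMT1 also without active thione replicate 1 (0.0518 and 0.128). No iron-using or respiratory gene rose or fell (0 of 22 and 0 of 36), and the Zap1 list had 1 riser, ATG41, and 1 faller, IZH4, the former lost without DMSO replicate 1 or 2 (edgeR adjusted p = 0.136 and 0.196) or active thione replicate 1 or 2 (0.128 and 0.0881).

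Further genes rising with the active thione were GTO3, RTS3 and TIR1, with log2 fold changes from 1.84 to 2.16. The largest fall was that of OPT1, an oligopeptide transporter, at -2.24 ± 0.28 (SE), followed by FMP48, IZH4, ARO9, WSC4, SAG1, ARO10, NCA3, PMA2 and THI7. These calls, and those of HIS4, ARG1, HIS3 and HIS5, were lost without DMSO replicate 1 (edgeR adjusted p from 0.0832 to 0.418) and without active thione replicate 2 (0.0636 to 0.362). All except OPT1 and FMP48 were lost without DMSO replicate 2 (0.0577 to 0.345), and 12 of the 17 without active thione replicate 1 (0.0538 to 0.173). ARO9, PMA2, THI7, HIS3 and HIS5 were lost without either inactive thione library (0.0516 to 0.0957). HIS4, ARG1, HIS3 and HIS5 rose in the amino acid list of 43 (11 when adjusted over the list alone; camera adjusted p = 7.77e-08, and 0.414 with an estimated correlation). HIS3 and HIS5 did not pass with the other size factors (edgeR adjusted p = 0.0577 for each). All 56 ribosome biogenesis genes had fold changes below 0 with a median of -0.36, yet none passed by itself (camera adjusted p = 6.48e-13, and 0.728 with an estimated correlation). With the preset correlation 9 more lists were called: unfolded protein response, proteasome, endocytosis and heat shock higher, and alpha cells, ribosomal proteins, ergosterol, stationary phase and respiration lower. With an estimated correlation their adjusted p-values were 0.101 to 0.837, and 8 of the 14 lists were called without DMSO replicate 1, where endocytosis, heat shock, ribosomal proteins, ergosterol, stationary phase and respiration had camera adjusted p from 0.0501 to 0.253. Other single libraries also ended calls, with camera adjusted p of 0.0503 and 0.0628 for ergosterol and stationary phase without CQ replicate 1, and 0.0767 for stationary phase without CQ replicate 2. Stationary phase and respiration were also lost with the other size factors (0.0554 and 0.0523), with the replicate block (0.0502 and 0.0736) and with RefSeq features only (0.0613 and 0.0545). Without active thione replicate 1 ribosomal proteins, stationary phase and respiration had 0.112, 0.254 and 0.709, without active thione replicate 2 heat shock, ergosterol and the proteasome 0.252, 0.309 and 0.0981, and without inactive thione replicate 1 or 2 respiration 0.0502 and 0.0528. In total 78 features changed, 63 higher and 15 lower. More were called with the compared groups alone (133), with the replicate block (174) and with DESeq2 (183). Only PHO5, PHO89, GIT1 and SPL2 stayed called whichever library was left out. The count was 4 without DMSO replicate 1, 9 without DMSO replicate 2, 27 and 7 without active thione replicates 1 and 2, and 45 and 43 without inactive thione replicates 1 and 2.

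The inactive thione at the same dose and time raised AZR1 from 0.555 ± 0.098 to 490 ± 88.1 CPM (SD, n = 2). AZR1 encodes a plasma-membrane drug transporter and lies on chromosome VII at 942806 to 944647. Its log2 fold change was 9.79 ± 0.35 (SE, edgeR adjusted p = 9.70e-07), or 886-fold. YOR1, an ABC drug-efflux pump at 1052824 to 1057257 on the same chromosome, rose by 1.34 ± 0.15 on the log2 scale, a call lost without DMSO replicate 1 or 2 (edgeR adjusted p = 0.273 and 0.144) and without inactive thione replicate 2 (0.104). GIT1, PHO89, SPL2 and PIR3 rose by 1.27 to 1.72, and FMP48 fell by 1.11. These 5 calls were lost without DMSO replicate 1 (edgeR adjusted p from 0.0918 to 0.720) and DMSO replicate 2 (0.0707 to 0.251). SPL2, PIR3 and FMP48 were lost without active thione replicate 1 or 2 (0.0740 to 0.112) and inactive thione replicate 2 (0.116 to 0.561), and PHO89, SPL2 and FMP48 without inactive thione replicate 1 (0.0773 to 0.151). FMP48 was also lost with the compared groups alone (0.0711). In total 9 features passed, 8 higher and 1 lower, against 739 at an unadjusted p under 0.05. The other 2 were CRG1 and ADH5, higher, named after their values were seen. With the replicate block 54 features passed.

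Camera called 9 lists with the inactive thione, and each call was lost with an estimated correlation. In the phosphate list 3 of 17 rose, 9 when adjusted over the list alone, with a median log2 fold change of 0.59 (camera adjusted p = 1.79e-12, and 0.232 with an estimated correlation). By edgeR 0 of 33 Aft1/Aft2, 6 Mac1, 23 Zap1, 22 iron-using or 36 respiratory genes passed. Ribosome biogenesis had a median of -0.37 (camera adjusted p = 0.734 with an estimated correlation). Camera also called ribosomal proteins, ergosterol and alpha-cell genes lower and general stress, unfolded protein response, proteasome and endocytosis higher, with adjusted p-values of 0.232 to 0.734 with an estimated correlation. Medians were -0.82 for alpha-cell, -0.29 for ergosterol and 0.56 for general stress genes. None of their members passed over all features, and adjusted over the list alone 3 of 4 alpha-cell and 11 of 27 ergosterol genes fell and 0 of 21 general stress genes passed. Without inactive thione replicate 2 ribosomal proteins, general stress, the proteasome and endocytosis were not called (camera adjusted p = 0.127, 0.147, 0.0584 and 0.565), nor were the proteasome and unfolded protein response without inactive thione replicate 1 (0.0629 and 0.153), endocytosis and the proteasome without DMSO replicate 1 (0.117 and 0.104) or the unfolded protein response without DMSO replicate 2 (0.0745). Endocytosis was not called without either CQ or either active thione library (0.0526 to 0.0609), with the other size factors (0.0547) or with RefSeq features only (0.0616). Only AZR1 stayed called whichever library was left out. The count was 1 without DMSO replicate 1 or 2, 4 without active thione replicate 1 or 2, 18 without CQ replicate 1 or 2 and 3 without inactive thione replicate 2, and DESeq2 called 84.

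Compared directly, at matched dose and time, the thiones differed in 7 features. TIS11, PHO89, PHO5, CTR1 and FRE1 were higher with the active thione, by 2.61 ± 0.29, 2.21 ± 0.19, 1.86 ± 0.20, 1.66 ± 0.16 and 1.60 ± 0.15 on the log2 scale (SE), with edgeR adjusted p from 0.00176 to 0.00499. CTR1, at 786208 to 787428 on chromosome XVI, stood at 76.0 ± 7.28 CPM with the active and 24.0 ± 1.11 with the inactive thione (SD, n = 2). AZR1 and YOR1 were lower with the active thione, by -8.50 ± 0.32 and -1.22 ± 0.15. The Aft1/Aft2, phosphate and Mac1 lists were higher with the active thione. Each had 2 members past the threshold, and 19 of 33, 9 of 17 and 3 of 6 when adjusted over the list alone, with medians of 0.52, 0.50 and 0.42. All 3 calls held with an estimated correlation (adjusted p = 0.0263 for each). So did that of a lower stationary-phase list (median -0.58, adjusted p = 0.0445), of whose 11 members 0 passed, and 1 was higher and 4 lower when adjusted over the list alone.

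**Figure D3:**
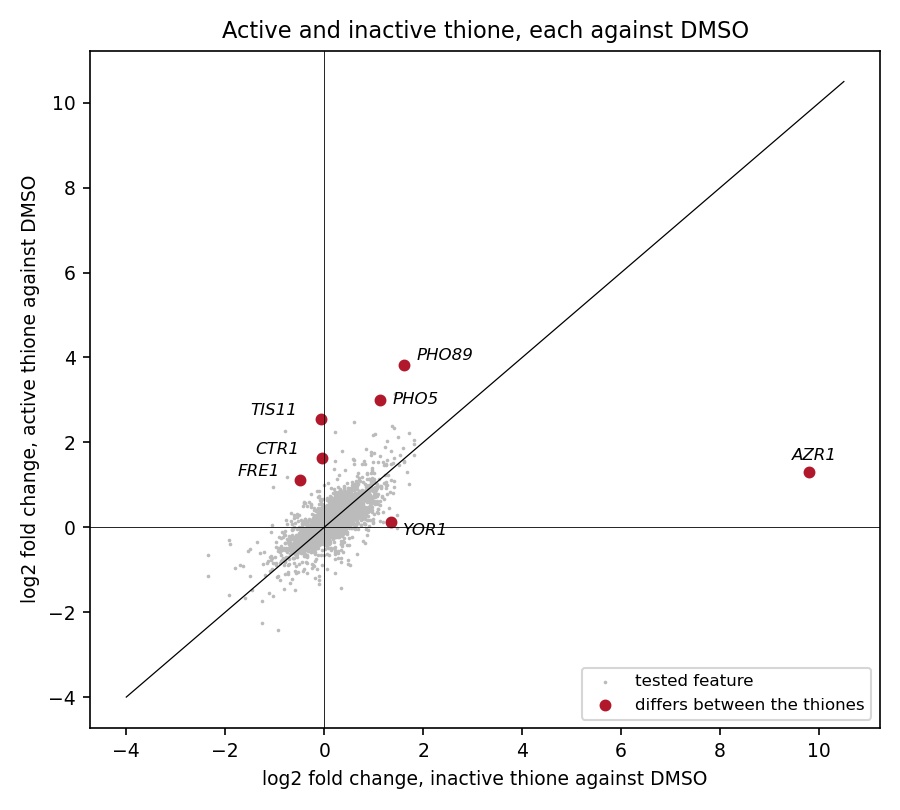
Each grey point is a tested feature, with its log2 fold change against DMSO for the inactive thione on the horizontal and for the active thione on the vertical axis, and the line marks equal values. The 7 red points differ between the thiones, with AZR1 at 9.79 for the inactive thione and PHO89 at 3.83 for the active one.

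Camera called 8 further lists between the thiones, each lost with an estimated correlation (adjusted p from 0.342 to 0.883). Amino acid, ergosterol and ribosomal protein genes were higher with the active thione, and general stress, respiration, iron-using, TCA and Pdr1/Pdr3 target genes lower. Without active thione replicate 1, 6 of these 8 were not called (camera adjusted p from 0.0970 to 0.530), without inactive thione replicate 2 ergosterol, TCA and Pdr1/Pdr3 targets (0.151 to 0.248), without active thione replicate 2 ribosomal proteins and Pdr1/Pdr3 targets (0.0589 and 0.106), without inactive thione replicate 1 the iron-using and respiratory lists (0.0522 and 0.304), and without either CQ library the Pdr1/Pdr3 targets (0.0585 and 0.0588). The Pdr1/Pdr3 call was also lost with the replicate block (camera adjusted p = 0.0522). It rests on YOR1, since the median of the 8 tested members was 0.02 and the mean -0.15. Without inactive thione replicate 2 the ribosomal protein list turned lower, with a median of -0.0533 (camera adjusted p = 0.0387). Ribosome biogenesis was not called, with a median of -0.0020. For 4998 of 5695 features (87.8%) the 95% interval of the difference between the thiones lay within 2-fold either way. The interval was 0.47 to 1.14 for FET3 and 0.03 to 0.76 for ZRT1 on the log2 scale, neither past the threshold (edgeR adjusted p = 0.180 and 1.00). PHO89 and AZR1 stayed called whichever library was left out. TIS11 lost its call without active thione replicate 2 or inactive thione replicate 1 (adjusted p = 0.0557 and 0.100) and with the compared groups alone (0.0616), PHO5 without active thione replicate 1 or 2 or inactive thione replicate 2 (0.0580, 0.0557 and 0.0520), and CTR1 and FRE1 without inactive thione replicate 2 (0.0520 each). YOR1 lost it without active thione replicate 1 or 2 or inactive thione replicate 2 (0.102, 0.255 and 0.141) and with the compared groups alone (0.0648). The count was 3 without inactive thione replicate 2, 4 without active thione replicate 2, and 26 with DESeq2.

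The doses of the active thione (20 µM) and CQ (0.8 µM) differ, so their values are set side by side only. All 22 iron-using genes and 35 of 36 respiratory genes were higher with the thione than with CQ, with medians of 3.41 and 2.96 on the log2 scale. In the Aft1/Aft2 list 28 of 33 were lower and 1 higher, with a median of -2.44. FIT3, FRE5, FIT2, ARN2 and ARN1 led the lower genes and CYC1, COX26, CYT1, CIR2 and SDH2 the higher ones. In the phosphate list 14 of 17 were higher with the thione, PHO5 by 4.49 ± 0.23 (SE). These 4 list calls held with an estimated correlation (adjusted p from 0.00310 to 0.0464). CTR1 was higher with the thione by 1.01 ± 0.15 and FRE1 lower, with -2.65 ± 0.15. Another 11 lists were called by camera and lost with an estimated correlation (adjusted p from 0.158 to 0.822). Amino acid, TCA, ergosterol, haem, Yap5, biotin, alpha-cell and sulfur genes were higher with the thione, and ribosome biogenesis and stationary-phase genes lower. Of 21 Yap1 targets 5 were higher and 1 lower, 7 and 3 when adjusted over the list alone, with a median of 0.02 and a mean of 0.63, so that call rests on few members. It was lost without CQ replicate 1 (median -0.08, camera adjusted p = 0.0863) and the sulfur call without CQ replicate 2 or active thione replicate 1 (0.143 and 0.0807). Altogether 969 features differed, 707 higher and 262 lower with the thione, a count that was 585 without active thione replicate 2 and 1593 without CQ replicate 2. Camera called the lists of Zap1, glycolysis, galactose, histone, S-phase, vacuolar proton pump, a-cell and meiosis genes in 0 of the 5 comparisons. Fry, which does not compare a list with other genes, called the meiosis list with CQ (lower, adjusted p = 0.0301) and, for the active thione against CQ, the meiosis and Zap1 lists (higher, 0.0304 and 0.0394). The Cup2 list and the mitochondrially encoded genes had fewer than 3 tested members.

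CQ and the active thione changed 34 genes in the same direction against DMSO, 28 higher and 6 lower, and 13 in opposite directions. Higher with both were TIS11, FIT2, SIT1, ENB1, FRE1, CTR1, PHO89 and GTO3, and lower with both were FMP48 and SAG1. Of the genes named here, PHO89 and FMP48 also passed in the same direction with the inactive thione. PHO5, GIT1 and SPL2 were among the opposite ones, lower with CQ and higher with the thione. Independent lists of these sizes would share 3.10 higher and 1.26 lower genes, and 20 simulations of unchanged groups against the same DMSO libraries shared at most 1. The first value leaves out the shared libraries and the second the real effects, so neither is a measure of chance for these 34. The DMSO libraries are common to both comparisons and could not be split, so part of the excess may come from them. Across the 5696 features, which are not independent replicates, the fold changes had r = 0.26 against 0.503 in the simulations, and a covariance of 0.0761 against 0.0351. With the inactive thione as the control of the active one, which removes the shared libraries, r was -0.029 and the covariance -0.00638. TIS11, FRE1, CTR1 and PHO89 were then higher in both comparisons, and 2 genes went opposite ways. YOR1 was lower in both, but against DMSO the active thione gave it a log2 fold change of 0.12 that did not pass, so it is no shared response. Against the same DMSO libraries, 7 of the 9 calls of the inactive thione were shared in direction with the active thione. CQ and the inactive thione shared 5, with 3 in opposite directions. Fold changes had r = 0.728 between the thiones and 0.276 between CQ and the inactive thione, against 0.494 and 0.506 in the simulations. The count of 34 fell to 1 without DMSO replicate 1, 4 without DMSO replicate 2, 14 and 3 without active thione replicates 1 and 2, and 21 without either inactive thione library.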

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

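Counts of called features kept within 1.5 times of the reported value with other size factors and without the filter in all 5 comparisons. They did so as well for features with a RefSeq entry only, a setting chosen after seeing the data (778, 62, 9, 7 and 969). For CQ against DMSO the other values were 399 at adjusted p under 0.01, 412 at 2-fold or more and 367 to 1419 with 1 library left out. For the active thione against DMSO they were 15 and 50 at those thresholds, 133 with the compared groups alone, 183 with DESeq2 and 4 to 108 with 1 library left out. The inactive thione against DMSO gave 2 at adjusted p under 0.01, 84 with DESeq2 and 1 to 18 with 1 library left out, the active against the inactive thione 26 with DESeq2 and 3 to 10, and the active thione against CQ 603 and 551 at those thresholds and 585 to 1593. A lone library left in a group is assumed to vary like the other groups. Stricter thresholds lower the counts by construction, and for the other changes the cause was not tested. Replicate numbers are shared between groups but not stated to pair libraries. Deviations of same-numbered libraries correlated at 0.33 to 0.43 among the DMSO, active and inactive thione groups, and at -0.15 to 0.21 between CQ and the others. A shared replicate effect in the DMSO and thione groups therefore stays possible, and the main fit leaves it in the spread. With the replicate block the counts were 952, 174, 54, 13 and 1171, and the shared response 67. The shared response was 5, YOR1 included, with the inactive thione as control and 1 to 42 with 1 library left out. List calls with camera numbered 14 for CQ, 14 and 9 for the active and inactive thione against DMSO, 12 between the thiones and 15 for the active thione against CQ. With an estimated correlation they were 3, 1, 0, 4 and 4. Fry, which does not compare a list with other genes, called 6 for the active and 4 for the inactive thione against DMSO and 5 between the thiones, and leaving out 1 library gave 8 to 15 lists for the active thione against DMSO. By the direction of the camera test a single list turned over, ribosomal proteins between the thiones, with medians from -0.0533 without inactive thione replicate 2 to 0.382 without inactive thione replicate 1. Medians near 0 changed sign in other lists as well, such as Yap1 targets for the active thione against CQ and Pdr1/Pdr3 targets between the thiones. With 1 library left out, 0 of the features called with all libraries changed sign in any of the 5 comparisons. Those features were picked for differences that passed, so a change of sign was unlikely from the start and its absence says little. At 12076141 to 19021672 counts depth limits only features of low count, such as FRE5 and LSO1 in DMSO, and for the other genes the spread between 2 replicates is the limit.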

Other observations

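The tests of the drug-response list, the DMSO libraries, the growth stage, the Crz1 list and HAP4 were chosen after the results were seen, as were the genes and terms of this paragraph. Among genes outside the fixed lists, those that fell with CQ were enriched for mitochondrial functions well beyond the respiratory enzymes. Of 92 genes annotated to mitochondrial translation 28 fell (hypergeometric test, adjusted p = 4.11e-09 over 1089 terms), among them MRPL3, MRPS9 and TUF1. Cytochrome c oxidase assembly had 12 of 26 genes lower (adjusted p = 9.94e-06), including SCO1, SHY1 and PET100, and cristae formation had 6 of 9 (adjusted p = 0.000939), including MIC10, MIC19 and MIC60. HAP4, the regulated subunit of the activator of respiratory genes, had a log2 fold change of -2.28 ± 0.17 (SE), while AFT1 itself rose by 1.66 ± 0.16. Among the genes that rose with CQ, 11 of 61 cell wall genes were the only enriched term (adjusted p = 0.0404), with TIR1, PIR3 and CRH1 among them.

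The fall of respiratory and iron-using genes with CQ was weighed against short messages being lost, the lower HAP4 level alone, and decay through AU-rich elements. Genes outside the fixed lists with coding lengths of 278 to 751 nt, the middle range of the respiratory list, had a median log2 fold change of 0.0436 over 1022 genes, which argues against a loss of short messages. All 12 iron-using genes outside the respiratory, TCA and haem lists fell, LEU1, BIO2 and RNR2 among them, which argues against a lower HAP4 level as the whole cause, provided that Hap4 does not control these genes, which was not tested. The sequence TTATTTAT, the kind of element Tis11 binds, stood within 300 nt after the stop codon of 135 of 472 genes that fell (28.6%) and of 5.21% of other tested genes, an odds ratio of 7.30 (two-sided Fisher p = 1.17e-51), but in the 300 nt before the start codon the odds ratio was 1.17, and 18 of 22 iron-using genes carried it. Message decay by Tis11 may therefore contribute, as a hypothesis that rests on fixed windows, since untranslated regions are not annotated; the 18 respiratory genes without the element had a median of -1.30 against -4.07 for the 18 with it, so other routes such as HAP4 stay open, and with the active thione, where TIS11 reached far lower levels, the 135 genes had a median of 0.0034.

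AZR1 and YOR1 rose with the inactive thione in cells without Pdr1 and Pdr3, and both lie on chromosome VII. The 24 other tested genes within 10 kb of either had a median log2 fold change of 0.0053 with quartiles of -0.12 and 0.19. This argues against extra copies of a segment that spans these genes. Their values ran from -0.48 to 0.93. A median over 24 genes cannot show transcription running in from a single neighbour, so that stays open. A general induction of drug-response genes through other factors was tested with 11 further targets ascribed to Yrr1 and Yrm1, of which 0 passed and for 8 of the 11 the 95% interval excluded a 2-fold rise, so an induction of most of them by 2-fold or more is unlikely. Smaller shifts stay open, since these 11 genes had a median of 0.30 (camera p = 0.0306 with an estimated correlation, not adjusted), though their medians with CQ and the active thione were 0.30 and 0.19, and they were not told apart between the thiones (p = 0.173). With CQ against DMSO AZR1 also rose, to a far lower level than with the inactive thione, while YOR1 fell, so the pair did not move together there. For the inactive thione a candidate explanation is a factor that acts on AZR1 and YOR1 with few other targets or weaker effects on them, which these data cannot name, and a mutation arising in these cultures was not tested.

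The rise of the phosphate regulon with the active thione might reflect the DMSO libraries, a later growth stage, or calcineurin signalling, since PHO89 is also a target of Crz1. On the second principal component the DMSO libraries lay above all treated ones, at 22.9 and 11.1. Replicate 1 also lay above replicate 2 there within each thione group, at 2.33 and -14.4 for the active and -2.06 and -19.3 for the inactive thione. The phosphate list was higher with the active than with the inactive thione, a comparison with no DMSO library (camera adjusted p = 0.0263 with an estimated correlation). The call also held with fry and, at the preset correlation, with other size factors and without the filter. An estimated correlation was not run with a library left out, and PHO89 and PHO5 were the only members that passed. These values argue against the DMSO libraries as the whole cause of the rise. The stationary-phase list had a median of -0.58 in that comparison (camera adjusted p = 0.0445 with an estimated correlation), the opposite of a later stage than with the inactive thione. Against DMSO the active thione gave the stationary-phase list a median of -0.06 (camera adjusted p = 0.396 with an estimated correlation). A later stage than in the DMSO cultures is therefore not decided. The 11 Crz1 targets had a median of 0.17 between the thiones, with all 11 intervals excluding a 2-fold rise, which leaves room for smaller shifts. Against DMSO that list had medians of 0.63 with the active thione, 0.40 with the inactive thione and 0.45 with CQ (camera p = 0.00547, 0.0155 and 0.0574 with an estimated correlation, not adjusted), so a joint signal through calcineurin and a response specific to phosphate both stay open, and for the inactive thione the part of the DMSO libraries is unresolved.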
